A study of Mus musculus with 7 samples.

How the data were processed

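The deposited data were log ratios of 7 arrays in 2 colours, 1 mouse liver per array, each against a pool of liver RNA from 6 wild-type mice. Per the labels' protocols, total RNA was extracted on silica spin columns with DNase treatment, amplified and labelled through aminoallyl coupling, with Cy3 in channel 1 and Cy5 in channel 2 on every sample. Per the series' design text, dyes were swapped in the profiling, and whether each deposited column merges both orientations is not given in the sources used here. The scanner software, background correction and normalization are also not given there, and scanner files were not used here. The deposited values were read as log10 ratios, although the authors' log base is not stated. The typical absolute deviation from the median was 1.05-fold to 1.10-fold per array in base 10 and 1.01-fold to 1.03-fold in base 2, and base 10 was taken since the latter is small for arrays of different mice. The tests do not depend on the base. Knockout liver 2 had the widest spread, with an SD over probes of 0.0975, against 0.0466 to 0.0676 on the other arrays. The medians of the columns were 0.0017, -0.0008, 0.0075 and 0.0072 for wild-type livers 1 to 4, and 0.0139, 0.0064 and 0.0054 for knockout livers 2 to 4. Centring near 0 was thus done before deposit, by a method that stays unknown. The direction, mouse over pool, is likely from the order of names in the titles and the channel labels, and stays unproven. If the wild-type mice of the arrays belong to the pool, a mouse cannot exceed 0.778 above a pool of 6 in log10. The wild-type maxima were 0.398, 0.684, 0.451 and 0.556 and their minima were -1.34, -1.30, -1.32 and -1.25, which goes with mouse over pool only under that condition. Across probes, the lowest correlation between 2 arrays was -0.250.

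Groups and numbers came from the titles, and the labels describe the animals as separate mice, 3 knockouts and 4 littermate controls. No pair of arrays had identical values in more than 0.119% of probes, so all 7 were kept as separate samples. The table had 0 unused value columns. Probes were named through the platform's annotation, updated by Entrez number for 17724 probes and by accession for 21 against the GRCm38.p6 gene table, while 79 kept the annotation's symbol. In all, 17824 probes had 1 symbol, 50 had several and 5700 had no listed gene, and 16462 distinct symbols were measured. The genome build of the probes is not given in the sources used here, so no coordinates are printed, and the assembly served only for names, chromosomes and distances between genes.

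Each probe was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, knockout minus wild type, two-sided), with Benjamini-Hochberg adjustment over all 23574 probes and a threshold of 0.05. The pool cancels in this difference. Every adjusted p of a single gene comes from this limma fit unless another test is named. The same fit tested the wild-type and the knockout mean against the pool. Errors are the SD over mice or the SE of the moderated fit, and fold intervals are at 95%. For gene lists, probes of a gene were averaged, and camera with a preset correlation of 0.01 was run on lists of at least 5 measured genes, adjusted over 29 lists. Camera with an estimated correlation, fry and an exact permutation of list means over the 35 splits of 7 arrays into 3 and 4 were run beside it. List members' values come from the limma fit of averaged genes. The 30 lists and their members were written before the data were examined, and each list is named in the results.

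C3ar1 was named first. The rule for other genes took, in each direction, up to 12 called genes with 1 symbol, no overlap between groups and no clone-type name, by size. Where under 5 passed, the 5 named genes of smallest p without overlap were given and said not to have passed. For each list, up to 4 members of smallest p could be named. Enrichment near C3ar1 was tested with Fisher's exact test on probes of placed genes within 10 Mb against all others, leaving out C3ar1.

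The steps were tested on simulated data of 23574 probes, in which 50 probes were changed at each of 4 sizes. Noise was drawn independently for each probe, with the SD of the moderated fit. At changes of 0.1, 0.2, 0.4 and 0.8 on the log10 scale, 6%, 82%, 100% and 100% were recovered in the comparison of knockout with wild type, with 8 false calls, and the 1 shifted list was called with 0 others. The recovery holds for that noise alone. Since simulated genes of a list did not vary together, the list result does not bear on false list calls in the real data. The alternatives tried were 3 other normalizations, a filter on variation, averaging of probes, robust and weighted fits, a replicate block, an ordinary test, each mouse left out, and other window sizes, thresholds and set tests. Their effect is given after the results.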

Results

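Liver RNA of 7 mice kept on a chow diet was profiled on 2-colour arrays. The mice were 3 knockouts of C3ar1, the gene of the receptor for the complement fragment C3a, and 4 wild-type littermates. Each array set the RNA of 1 mouse against a common pool made from the livers of 6 wild-type mice. The deposited table held a log ratio for 23574 probes on every array, with no value missing, of which 17824 probes carried 1 gene symbol. The wild-type livers are numbered 1 to 4 and the knockout livers 2 to 4, as in the labels. Positive values most likely mean a higher signal in the mouse than in the pool, since the titles name the pool first and the mouse second, and the mouse's place goes with the Cy5 channel. Neither this direction nor the base of the logarithm is given in the sources used here. Base 10 was assumed for every fold printed, and a turned direction would turn every sign. The number of arrays limits the precision.

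The targeted gene was read first. The single probe of C3ar1 gave 0.0042, 0.0337 and 0.0514 in knockout livers 2, 3 and 4. In wild-type livers 1 to 4 it gave -0.0296, -0.0318, 0.0225 and 0.0264. The mean was 0.0298 ± 0.0238 in the knockouts and -0.0031 ± 0.0319 in the wild types (SD). The difference of 0.0329 ± 0.0233 (SE) was smaller than the spread between mice could separate (limma, adjusted p = 0.884). The deleted part of the gene is not given in the sources used here, so this probe can lie outside it and checks neither the labels nor the direction. Whether the probe read above background in liver is also unknown, since signal over background was not analysed here.

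The main question was which liver genes differed between the genotypes. A single gene passed the test over all 23574 probes, A2ml1, a protease inhibitor of the alpha-macroglobulin family encoded on chromosome 6. A2ml1 was lower in the knockouts, at -0.749 ± 0.0532 (SD) against 0.0774 ± 0.0962 in the wild types, and the groups did not overlap. The difference of -0.827 ± 0.0528 (SE) corresponds to 6.71-fold in base 10, with a 95% interval from 5.06 to 8.90 (limma, adjusted p = 0.0106). No probe was higher in the knockouts past the threshold by limma. At an unadjusted p under 0.05 limma listed 1054 probes, 439 higher and 615 lower, against 1178.7 expected by chance. The ordinary test, which does not pool the spread across probes, listed 949 at that level and called 0. The groups did not overlap in 5.26% of probes, where chance gives 5.71%.

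The other genes of smallest p did not pass. Clec2h, which encodes a C-type lectin-like membrane protein, stood at -0.765 ± 0.0319 in the knockouts and -0.0336 ± 0.146 in the wild types, 5.39-fold apart (adjusted p = 0.101). Slc15a5, a member of the peptide transporter family, stood at -0.545 ± 0.0363 and 0.0510 ± 0.118, 3.94-fold apart (adjusted p = 0.101). Apol7c, of the apolipoprotein L family, and Dera, the deoxyribose-phosphate aldolase, read lower in the knockouts by 1.39-fold and 1.89-fold (adjusted p = 0.225 and 0.364). In the other direction, the centrosomal protein gene Tacc2 differed by 0.185 ± 0.0210 (SE), or 1.53-fold, with an adjusted p of 0.174. This value rests on 1 of the 2 probes of Tacc2, since the other differed by 0.0225 and the average of both by 0.104. The differences were 0.128 ± 0.0182 for Pprc1, a transcriptional coactivator, and 0.173 ± 0.0258 for the pseudokinase gene Nrbp2 (adjusted p = 0.413 and 0.456). Rhno1, a DNA damage checkpoint gene, differed by 0.198 ± 0.0363, and Pfkl, the liver phosphofructokinase, by 0.117 ± 0.0223, both with an adjusted p of 0.884. In each of these 9 genes and A2ml1 all 3 knockout values lay on one side of all 4 wild-type values, which was a condition of the rule that chose them.

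**Figure D1:**
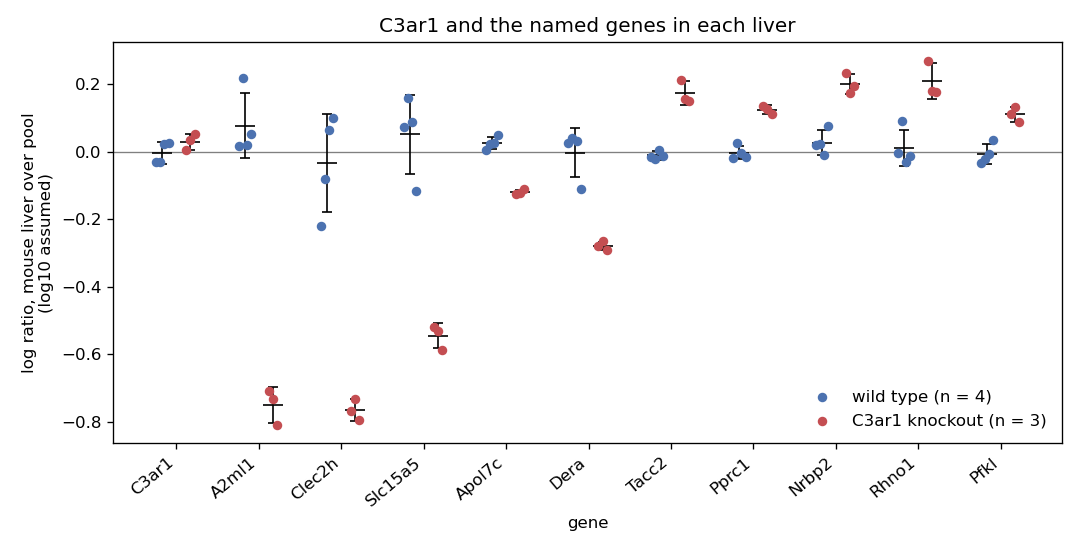
Log ratio of each mouse liver over the wild-type pool (log10 assumed, vertical axis) for C3ar1 and 10 named genes (horizontal axis), with 1 point per liver, horizontal marks for group means and bars for 1 SD (4 wild types, 3 knockouts). The knockout values of A2ml1 lie between -0.809 and -0.708, below all 4 wild types, while the groups overlap for C3ar1.

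The call of A2ml1 was lost when single arrays were left out, while its difference changed little. Without knockout liver 2, 3 or 4 the difference was -0.848, -0.836 or -0.797 (adjusted p = 0.0765, 0.114 or 0.0723). Without wild-type liver 3 it was -0.846 (adjusted p = 0.0664). The call was also lost after quantile normalization (adjusted p = 0.0511), after scale normalization (0.963), with a replicate block (0.0765) and in the ordinary test (0.519). Over all 17 alternatives the adjusted p of A2ml1 ranged from 2.67e-06 to 0.963.

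C3ar1 lies on chromosome 6 in the GRCm38.p6 annotation, which was used for distances only. The called gene, A2ml1, is 1 of 238 probes whose genes lie within 10 Mb of C3ar1, against 0 called of 17506 placed probes elsewhere (Fisher's exact test, two-sided, p = 0.0134). With 1 called probe this p is only the share of placed probes that lie in the window. At an unadjusted p under 0.05 the share was 9.24% within this window and 4.69% elsewhere (Fisher's exact test, p = 0.00299). At an unadjusted p under 0.01, a level chosen after seeing the data, it was 5.46%, or 13 probes, and 0.765% elsewhere (Fisher's exact test, p = 9.32e-08). Between 10 and 20 Mb 10 of 81 probes were at that level, or 12.3%, while from 20 to 40 Mb the share was 0.939%, and 0.716% on other chromosomes. Of the 18 placed probes among the 20 smallest p values, 7 lay within 20 Mb of C3ar1, a region that holds 1.80% of placed probes.

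Genes of this region read both lower and higher in the knockouts. Besides A2ml1, Clec2h, Slc15a5 and Dera, the lower ones included Ift122, a gene of ciliary transport (-0.232 ± 0.0348, SE), the proapoptotic gene Bid (-0.209 ± 0.0364) and Mgst1, a microsomal glutathione transferase (-0.294 ± 0.0598). The higher ones included Rhno1, Pik3c2g, a lipid kinase (0.521 ± 0.119 in 1 of its 2 probes, and -0.0149 in the other), and Apobec1, the editing enzyme of apolipoprotein B RNA (0.279 ± 0.0584). Their adjusted p values over all probes ranged from 0.456 for Ift122 to 0.884 for Pik3c2g, so they did not pass singly. Ift122, Bid, Mgst1, Pik3c2g and Apobec1 were chosen after their values were seen. Within 5 Mb 0 probes were called, and the share at an unadjusted p under 0.05 was 6.72%, against 4.74% elsewhere (Fisher's exact test, p = 0.302). At an unadjusted p under 0.01 it was 4.48% within 5 Mb (Fisher's exact test, p = 0.000878). Within 20 Mb the share at an unadjusted p under 0.05 was 11.3%, against 4.63% elsewhere (Fisher's exact test, p = 1.54e-06). Without knockout liver 3 the share at an unadjusted p under 0.05 was 8.82% within 10 Mb and 7.14% elsewhere (Fisher's exact test, p = 0.310).

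**Figure D2:**
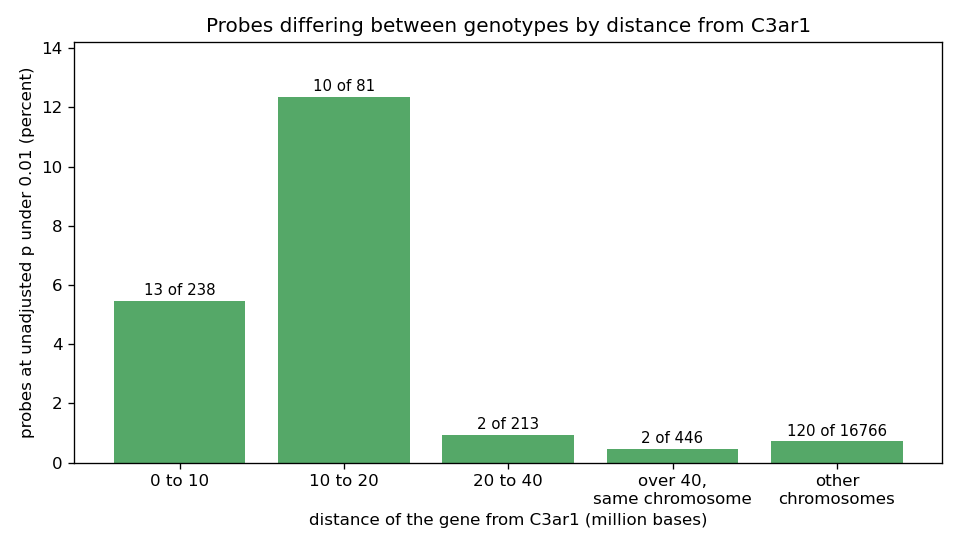
Percent of probes at an unadjusted p under 0.01 between knockout and wild-type livers (vertical axis) by distance of their gene from C3ar1 in Mb (horizontal axis), with the number of such probes above each bar. The share is 5.46% from 0 to 10, 12.3% from 10 to 20 and 0.716% on other chromosomes.

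Gene lists fixed before the data were examined were used to ask whether groups of liver genes differed together. Of 29 lists tested, 11 were called by camera with its preset correlation between genes of 0.01, 6 toward higher and 5 toward lower values in the knockouts. None of the 11 held when the correlation was estimated for each list, where the smallest adjusted p was 0.648. The fry test called 0 lists, with 0 at an unadjusted p under 0.05. Of the 631 member entries measured, 0 passed over all genes. The mean of 1 list, that of stellate cell and fibroblast markers, separated the genotypes at the smallest p that 35 splits of the arrays can give (exact permutation test, two-sided, p = 0.0286, adjusted over 29 lists 0.8286). The number of lists called by camera was 2 without knockout liver 4 and 5 without wild-type liver 3. The median difference over all probes was 0.00555, and 0.000883 to 0.00358 under the other scalings. The mean differences of the 11 called lists kept their sign under each of these, and 2 of the lists lost their call under some scaling.

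Markers of endothelial cells were higher in the knockouts in 16 of 21 genes, with a mean difference of 0.0402 (camera, adjusted p = 0.00219, and adjusted p = 0.648 with an estimated correlation). Vwf, the von Willebrand factor gene, differed by 0.0745, the scavenger receptor gene Stab1 by 0.102 and Egfl7 by 0.0698, and 0 passed when adjusted over the list alone. The list mean difference was 0.0242 without wild-type liver 3 and 0.0174 without knockout liver 4, and the call was lost in both, while with array weights it was 0.0235 and called. Vwf itself lies within 10 Mb of C3ar1. Stellate cell and fibroblast markers were higher in 18 of 21 genes, by 0.0391 on average (adjusted p = 0.0133, and adjusted p = 0.648 with an estimated correlation). Their collagen genes Col1a2 and Col1a1 differed by 0.0813 and 0.147. That list was not called without wild-type liver 3 (0.0299) or knockout liver 4 (0.0194). Acute phase genes, which encode plasma proteins of inflammation, were higher in 25 of 28, by 0.0538 on average (adjusted p = 0.0133, and adjusted p = 0.648 with an estimated correlation). The heme-binding Hpx differed by 0.118 and the protease inhibitor Serpina3n by 0.122. The list mean was 0.149 in knockout liver 4 and 0.0125 or below in the other knockouts, against 0.0765 in wild-type liver 1. The difference turned to -0.00230 without knockout liver 4 and was 0.0254, not called, without wild-type liver 3, while it was called at 0.0848 without wild-type liver 1 and 0.0975 without knockout liver 2. Immediate early genes were higher in 20 of 25, by 0.0420 (adjusted p = 0.0266, and adjusted p = 0.648 with an estimated correlation), led by the stress-inducible Gadd45g at 0.358 ± 0.108 (SE). Their list means did not overlap between the genotypes, and other splits of the arrays gave as large a difference (exact permutation test, two-sided, p = 0.0857). The camera call was lost without wild-type liver 3 (0.0239) or knockout liver 4 (0.0413).

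Complement and coagulation genes, the system to which C3ar1 belongs, were higher in 28 of 38, by 0.0284 on average (adjusted p = 0.0302, and adjusted p = 0.733 with an estimated correlation). Vitronectin (Vtn) and C4b differed by 0.114 and 0.0692, while Mbl2, a mannose-binding lectin, differed by -0.0763. The list difference was 0.0171 without wild-type liver 1, 0.00531 without knockout liver 4 and 0.0179 with array weights, and none of these was called. Genes of glucose and glycogen metabolism were higher in 16 of 22, by 0.0453 (adjusted p = 0.0413, and adjusted p = 0.733 with an estimated correlation). Pfkl passed when adjusted over the list alone (limma, adjusted p = 0.0201), and Pck1, the gluconeogenic carboxykinase, differed by 0.134. This call was lost without wild-type liver 1 (0.0219) or 3 (0.0336) and without knockout liver 2 (0.0288) or 3 (0.0269), and the difference was larger and called without wild-type liver 2 (0.0691), without knockout liver 4 (0.0802) and with array weights (0.0726). In all 6 of these lists 0 members passed over all genes. List means of complement and of endothelial, stellate and macrophage markers were highest in knockout liver 4, at 0.0675, 0.0481, 0.0371 and 0.0935.

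Female-biased liver genes were lower in the knockouts in 18 of 20, by -0.0839 on average (camera, adjusted p = 0.00219, and adjusted p = 0.648 with an estimated correlation). Hao2 and the cytochrome gene Cyp2a4 differed by -0.195 and -0.215. Their list mean was -0.258 in knockout liver 4 and 0.0270 and 0.0297 in the other knockouts, and without liver 4 the difference turned to 0.0115. It was called at -0.0537 without wild-type liver 1 and at -0.131 and -0.132 without knockout livers 2 and 3. Genes of cholesterol synthesis and uptake were lower in 18 of 20, by -0.0648 (adjusted p = 0.00695, and adjusted p = 0.735 with an estimated correlation). The sterol enzymes Msmo1 and Hmgcs1 differed by -0.219 and -0.158, and the highest list mean was 0.207 in wild-type liver 2. Without that liver the difference was -0.00907, and without knockout liver 4 it was -0.0553, neither of them called, while it was -0.0989 and called without wild-type liver 1. Genes of the citric acid cycle and respiratory chain were lower in 23 of 30, by -0.0255 (adjusted p = 0.0133, and adjusted p = 0.648 with an estimated correlation), with Ndufs1 at -0.0814 and Sdha at -0.0878. It was not called without wild-type liver 2 (-0.0200) or knockout liver 4 (-0.0142), with the less variable probes left out (-0.0312) or with array weights (-0.00207), and was called at -0.0432 without knockout liver 3. Array weights also ended the calls of the female-biased genes (-0.0325) and of the cholesterol genes (-0.0305).

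Interferon response genes were lower in 15 of 24, by -0.0329 (camera, adjusted p = 0.0302, and adjusted p = 0.648 with an estimated correlation). The chemokine gene Cxcl10 differed by -0.241 and Ifit3 by -0.0972, 4 members lay below an unadjusted p of 0.05, and 0 passed when adjusted over the list alone. The difference was -0.00782 without knockout liver 3, -0.0216 without wild-type liver 1 and -0.0362 without wild-type liver 3, and none of these was called. Nor was it called after quantile (-0.0176) or scale normalization (-0.0261), or with the less variable probes left out (-0.0351). It was larger and called with array weights (-0.0653) and without knockout liver 4 (-0.0572). Genes of fatty acid oxidation and PPAR-alpha targets were lower in 23 of 33, by -0.0543 (adjusted p = 0.0413, and adjusted p = 0.806 with an estimated correlation). The dehydrogenase gene Acadm differed by -0.161 and the fatty acid transporter gene Cd36 by -0.357. The list mean was -0.206 in knockout liver 4 and -0.157 in wild-type liver 2, and without knockout liver 4 the difference turned to 0.0191. It was -0.0174 without wild-type liver 1 and -0.0380 without wild-type liver 3, and neither was called. The call was also lost after median centring (-0.0590) and with the less variable probes left out (-0.0628), and kept with larger differences without wild-type liver 2 (-0.105) and knockout liver 2 (-0.112).

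**Figure D3:**
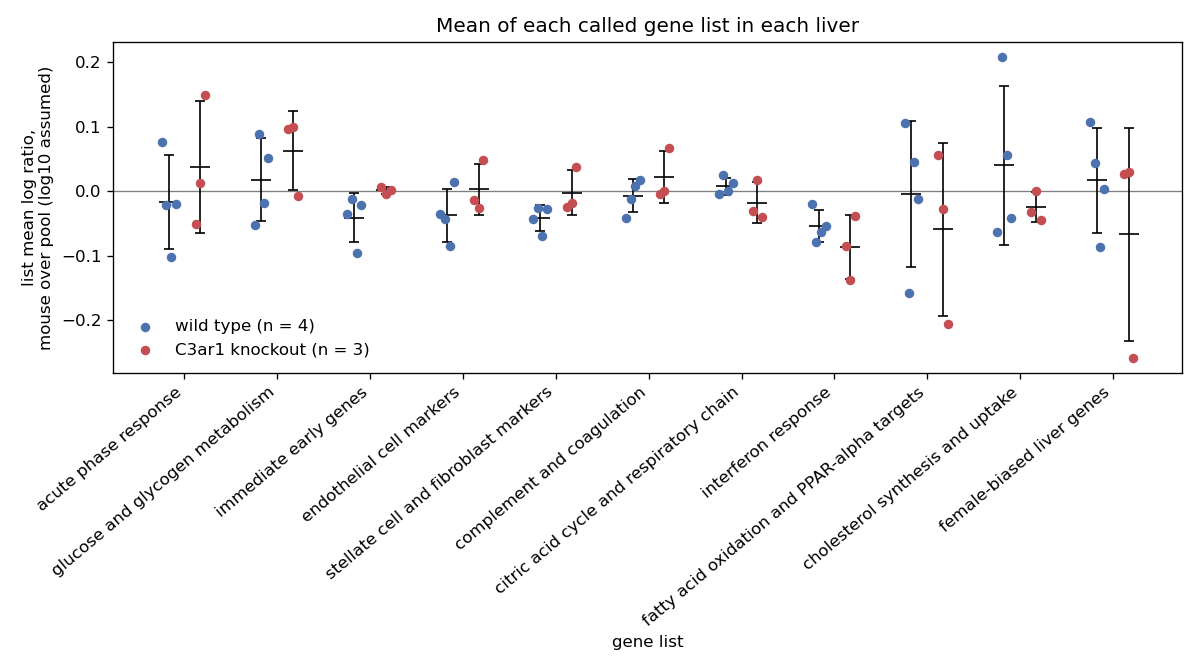
Mean log ratio over the members of each called gene list in each liver (log10 assumed, vertical axis), for 11 lists (horizontal axis), with 1 point per liver, horizontal marks for group means and bars for 1 SD (4 wild types, 3 knockouts). The genotypes overlap in 9 of the 11 lists, all but those of stellate cell and fibroblast markers and of immediate early genes, and knockout liver 4 lies at -0.258 for the female-biased genes.

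The other cell type lists were not called by camera. Of the 18 lists tested and not called, 10 were called under at least 1 alternative, and the difference of 8 turned sign without knockout liver 4. Macrophage and Kupffer cell markers were higher in 20 of 22 genes, by 0.0548 on average (adjusted p = 0.0511), with the scavenger receptor gene Marco at 0.365 ± 0.154 (SE). The list mean was -0.138 and -0.163 in knockout livers 2 and 3 and 0.0935 in liver 4, against -0.124 on average in the wild types, and without knockout liver 4 the difference turned to -0.0265. Marco read -0.386 in knockout liver 3, below all 4 wild types. The list was called under median centring (0.0501), quantile normalization (0.0859) and scale normalization (0.0795), and was not called with array weights (0.00507) or without wild-type liver 3 (0.02001). With its correlation estimated, at 0.617, it was not called (adjusted p = 0.804), and none of the 18 lists was. Neutrophil markers differed by 0.0126 (adjusted p = 0.177), with the elastase gene Elane at 0.0442. Lymphocyte markers differed by 0.00631 (adjusted p = 0.596). In that list Klrb1c, a natural killer cell receptor gene that lies within 10 Mb of C3ar1, was lower by -0.157 and passed when adjusted over the list alone (limma, adjusted p = 0.0308). Erythroid markers differed by -0.0291 (adjusted p = 0.156), with the globin gene Hbb-b1 at -0.141, and by -0.0170 without wild-type liver 4. Bile duct cell markers differed by -0.0324 (adjusted p = 0.268), pancreas markers by 0.0163 (adjusted p = 0.205) and adipose tissue markers by -0.116 (adjusted p = 0.205). Bile duct markers were called without wild-type liver 1 (-0.0524), and their difference turned sign without wild-type liver 2. Adipose markers were called without wild-type liver 2 (-0.166) but not without knockout liver 4 (-0.0642). The adipose mean rested on the lipid droplet genes Cidea and Cidec at -0.974 and -0.416, since the list median was -0.0119. Cidec lies within 10 Mb of C3ar1. Without the list's members near C3ar1, a setting chosen after seeing the data, the difference was -0.0903 and not called. Antigen presentation genes differed by 0.00532 (adjusted p = 0.587).

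The metabolic, secretory and regulatory lists left also were not called by camera. Hepatocyte secreted proteins were higher in 19 of 25 genes, by 0.0246 (adjusted p = 0.0716), with the transferrin gene Trf at 0.0956, and were called with the less variable probes left out (0.0318), with array weights (0.0218) and without wild-type liver 4 (0.0293), but not without wild-type liver 1 (0.0170) or knockout liver 2 (0.0141). Xenobiotic metabolism genes differed by -0.0181 (adjusted p = 0.128), with Aldh1a1 at -0.116, and were called without knockout liver 2 (-0.0314) or 3 (-0.0474). Their difference turned sign without knockout liver 4 and with array weights. Fatty acid and triglyceride synthesis genes differed by -0.0111 (adjusted p = 0.512), and by 0.00428 after quantile normalization, with the acyltransferase gene Gpam at -0.104. They were called without wild-type liver 1 (-0.0628), and turned to 0.0421 without wild-type liver 2, 0.0250 without knockout liver 4 and 0.0279 with array weights, not called in these 3. Male-biased liver genes differed by 0.0644 (adjusted p = 0.138), with Elovl3 at 0.116. They were called after scale normalization (0.0919), with the less variable probes left out (0.0788), with array weights (0.0596), without wild-type liver 3 (0.117) and without knockout liver 2 (0.1002). Without wild-type liver 1 the difference was 0.0157 and without knockout liver 4 it was 0.0211, neither called. Endoplasmic reticulum and amino acid stress genes differed by 0.0156 (adjusted p = 0.538), and there the transcription factor gene Atf4, at 0.0744, passed when adjusted over the list alone (limma, adjusted p = 0.0364). That list was called without knockout liver 2 (0.0496), and its difference turned sign without knockout liver 4. Circadian clock genes differed by 0.00648 (adjusted p = 0.860), with Per3 at 0.0621. Cell cycle genes had a mean difference of -0.0115 and a median of 0.00283 (adjusted p = 0.177), with the helicase gene Mcm4 at -0.127, and were called without wild-type liver 1 (-0.0183). Mean and median also had opposite signs for bile acid and sterol metabolism (-0.0207 and 0.00918, adjusted p = 0.688), amino acid catabolism and urea cycle (-0.000319 and 0.00285, adjusted p = 0.759) and the heat shock response (-0.000224 and 0.00337, adjusted p = 0.587). The bile acid difference was -0.00418 without knockout liver 4, -0.0368 without knockout liver 3 and -0.00150 with array weights. The fry direction was upward for the bile acid and amino acid lists, against a downward camera direction. The mean difference of the amino acid list was 0.0116 after quantile and 0.00359 after scale normalization, and that of the heat shock list 0.0151 and 0.0104. Of these, the ornithine aminotransferase gene Oat differed by -0.2002, the bile acid enzyme gene Akr1d1 by -0.192 and the chaperone gene Dnaja1 by -0.0872. Of the sex chromosome-linked list 2 genes were measured, too few for a set test, and Kdm5d and Uty differed by -0.0263 and 4.17e-05. Their mean, -0.0131, became 0.00806 after quantile and 0.00320 after scale normalization.

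Each genotype was also set against the pool. In the wild-type livers 0 of 23574 probes differed from the pool by limma, with 546 at an unadjusted p under 0.05, and the ordinary test also called 0. The smallest adjusted p, 0.0780, belonged to Moxd1, a monooxygenase gene, at -1.23 ± 0.103 (SE), and Moxd1 was also at -0.971 ± 0.119 in the knockouts (adjusted p = 0.0902). Moxd1 passed in the wild types when knockout liver 4 was left out of the fit, and Dmbt1, a mucosal defence gene, passed when wild-type liver 2 was left out. In the knockout livers 8 probes differed from the pool, 2 above it and 6 below, with 4148 at an unadjusted p under 0.05. Chance gives 1178.7 such probes for either genotype. Tacc2 (0.174 ± 0.0159, SE) and Nrbp2 (0.2002 ± 0.0195) were above the pool (adjusted p = 0.0351 for both), while the second probe of Tacc2 was at -0.00697 in the knockouts. A2ml1, Clec2h, Slc15a5 and Dera, all on chromosome 6, were below it, with adjusted p values of 0.00275, 0.0129, 0.0256 and 0.0422. The remaining 2 probes had no listed gene and stood at -0.412 and -0.343. Whether the wild-type mice of the arrays belong to the pool is not given in the sources used here. If they do, their values are drawn toward 0, so the counts of the genotypes against the pool are not compared. The same pool is on every array, so an offset of the pool or of a dye can repeat on each array. The test against the pool counts such an offset as a difference. Of these 8 probes, A2ml1 alone passed the test of the difference between the genotypes. Moxd1 and Dmbt1 were chosen after their values were seen.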

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

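The tests below were chosen after the values they bear on were seen, except the test of 6 further probes, which was set before those probes were looked at. Of 40 values tested for a wild-type liver far from the other 3, 2 stood apart, and chance gives about 2. The mean of the cell cycle list was -0.0150 in wild-type liver 1 and between 0.0107 and 0.0138 in the others. Dera read -0.110 in wild-type liver 4 and 0.0250, 0.0413 and 0.0319 in livers 1 to 3, against -0.291 to -0.266 in the knockouts.

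Dera is 1 of 10 genes between 10 and 20 Mb from C3ar1 that differed between the genotypes at an unadjusted p under 0.01, all on the same side of C3ar1. Wild-type liver 4 was the wild type closest to the knockout mean in 10 of these 10, among them Mgst1 (-0.173), Slc15a5 (-0.116) and Pik3c2g (0.251). Its position, with the mean of the other wild types at 0 and the knockout mean at 1, had a median of 0.555 and ranged from 0.343 to 0.697. Within 10 Mb liver 4 was closest in 3 of 13 such genes, with a median position of -0.0112.

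A general likeness of this array to the knockouts cannot be told apart: over all probes liver 4 was the wild type best correlated with each knockout (0.607, 0.429 and 0.121), and on other chromosomes it was closest in 30% of the 120 such probes, more often than any other wild type. Its median position there was 0.0799 (range -0.584 to 0.700) against 0.555 in the 10 genes, so by this measure the likeness elsewhere was smaller, though the ranges overlap. A candidate explanation is that this mouse carried 1 copy of a segment linked to the targeted allele on that side, and the contrast with other chromosomes (Fisher's exact test, p = 1.53e-05) comes from the same genes in which it was noticed, which as neighbours on 1 array are not independent. The prediction set beforehand for this explanation was not met: of 6 further probes farther than 10 Mb on that side, with p from 0.01 to 0.05, liver 4 was closest in 1, against 34.7% on other chromosomes (Fisher's exact test, p = 0.670). These 6 probes were few and not limited to 10 to 20 Mb, so they cannot exclude a segment confined to that range. For the 10 genes both explanations stay open, no genotype of the flanking region was analysed here, and no biological explanation was tested.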

How the results depend on the processing

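Unless said otherwise, the alternatives were planned before the data were examined, and the cause of a change was not tested. The planned scale method could not run on log ratios with negative medians. What is called scale normalization throughout set equal median absolute values per array in its place, a substitute that was not planned. The 1 probe called by limma became 0 after quantile normalization, scale normalization, in the ordinary test without pooling across probes and with a replicate block (834, 863, 949 and 543 at an unadjusted p under 0.05), and 4 when the probes of lower variation were left out, all 4 lower (A2ml1, Clec2h, Slc15a5 and 1 unnamed probe), where fewer probes are tested and the prior comes from the variable ones. It was 1 under median centring, averaged probes, probes of 1 symbol, robust and weighted fits and at adjusted p under 0.10. Leaving out each mouse gave 0 to 3, with 0 without any 1 knockout or wild-type liver 3, 2 without wild-type liver 1 and 3 without wild-type liver 4. A2ml1 was below the wild types in all 17 alternatives, from -0.848 to -0.701, and past the threshold in 9, with adjusted p from 2.67e-06 to 0.963. C3ar1 kept its sign and stayed short of the threshold in every alternative run, but was not among the more variable probes.

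The 11 called lists became 0 with an estimated correlation, 0 by fry and 0 by exact permutation of list means (chosen after seeing the data), and ranged from 2 to 14 with each mouse left out. Other settings gave 9 to 13. With each mouse left out, the acute phase difference ranged from -0.00230 to 0.0975, that of fatty acid oxidation from -0.112 to 0.0191 and that of female-biased genes from -0.132 to 0.0115. Each turned sign without knockout liver 4. Of the lists not called, 11 turned sign somewhere. The amino acid list was at 0.0116, 0.00359, 0.0371 and 0.000308 after quantile normalization, after scale normalization, with array weights and with the most variable probe per gene. Fatty acid synthesis was at 0.00428 after quantile normalization and 0.0279 with array weights, and the heat shock list at 0.0151, 0.0104 and 0.00134 after quantile normalization, after scale normalization and with the block. Array weights gave -0.0159 for antigen presentation, -0.0136 for lymphocyte markers, -0.000960 for neutrophil markers and 0.0177 for xenobiotic metabolism, and antigen presentation was at -0.000199 with the less variable probes left out. With each mouse left out, the ranges were -0.0247 to 0.0408 for the amino acid list, -0.00770 to 0.0222 for antigen presentation, -0.0524 to 0.00605 for bile duct, -0.00307 to 0.0206 for circadian, -0.0313 to 0.0496 for endoplasmic reticulum stress, -0.0628 to 0.0421 for fatty acid synthesis, -0.0336 to 0.0214 for heat shock, -0.00714 to 0.0219 for lymphocyte, -0.0265 to 0.102 for macrophage, -0.00399 to 0.0254 for neutrophil and -0.0474 to 0.0246 for xenobiotic genes. Lists not called that kept their sign ranged from -0.167 to -0.0642 for adipose, -0.0368 to -0.00418 for bile acid, -0.0183 to -0.00873 for cell cycle, -0.0399 to -0.0170 for erythroid, 0.0141 to 0.0335 for hepatocyte secreted, 0.0157 to 0.117 for male-biased and 0.00759 to 0.0232 for pancreas genes. The called share near C3ar1 fell to 0 in the window of 5 Mb, since A2ml1 lies outside it, and the excess at an unadjusted p under 0.05 also missed the threshold there (6.72% against 4.74%) and was larger in the window of 20 Mb (11.3% against 4.63%). At an unadjusted p under 0.05 with each mouse left out (chosen after seeing the data) it ranged from 7.14% to 11.8%, and without knockout liver 3 the excess missed the threshold. The 0 wild-type probes differing from the pool became 1 (Moxd1) with the less variable probes left out, and 0 to 1 with each mouse left out.

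The shared numbers did not pair the mice, with correlations of -0.137, -0.205 and -0.154 between same-numbered deviations, none the best match. With the block, where wild-type liver 1 has no partner, 0 probes were called, the calls of the complement, glucose, interferon and fatty acid oxidation lists were lost (0.0171, 0.0219, -0.0216 and -0.0174), and those of bile duct, cell cycle, erythroid, fatty acid synthesis, macrophage and xenobiotic lists were gained (-0.0524, -0.0183, -0.0382, -0.0628, 0.0628 and -0.0230). The filter for missing values was not run, as none were missing, nor the 1.5-fold threshold, as the log base is not settled. Signal over background was not analysed here, so what it limits is unknown.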

Other observations

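The tests given here were chosen after the results they bear on were seen, except the count near C3ar1 and the estimated correlation, which were planned. Several liver genes varied widely between mice. Dmbt1, a mucosal defence gene, read 0.684 in wild-type liver 2 and between -1.397 and -1.25 in the other 6 livers. The acute phase genes Saa1, Saa2 and Saa3 were at 0.353, 0.337 and 0.342 in wild-type liver 1 and at 0.760, 0.901 and 0.772 in knockout liver 4, and below 0 in the other 5 livers. Knockout liver 4 had the lowest values of Cidec (-1.04), Plin4 (-0.691), Cd36 (-0.745) and 1 of the 2 probes of Cyp4a10 (-0.824, the other at 0.0108), but not of Lpin1 (-0.183, and -0.305 in wild-type liver 3). The heme synthesis gene Alas1 stood at -0.938 in that liver and between -0.0864 and 0.264 in the others. Cidea, another lipid droplet gene, was low in all 3 knockouts and in wild-type liver 2, at -1.365 to -0.640 and -0.945, with means of -1.07 in the knockouts and -0.0918 in the wild types (limma, unadjusted p under 0.05, adjusted p = 0.884). In that wild-type liver Mmp7, a matrix metalloproteinase gene, and the glucose transporter gene Slc2a4 were at 0.594 and 0.587, and below 0 in the other 6. These genes were chosen after their values were seen.

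Correlations between arrays over all probes did not follow genotype alone, and no clustering was run. Across probes, which are not independent replicates, the highest correlation was 0.607, between wild-type liver 4 and knockout liver 2. The knockouts correlated at 0.540, 0.209 and 0.178 with each other, and wild-type liver 1 with knockout liver 4 at -0.250. Among the wild types the correlations ranged from -0.163 to 0.330. The shared pool enters every log ratio, so these correlations do not measure the likeness of livers alone.

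Probes within 10 Mb of C3ar1 differed more often than others, and a candidate explanation is sequence of another strain carried along with the targeted allele, which the planned count (Fisher's exact test, p = 0.00299) does not set above others, as it is the pattern itself and treats neighbouring probes as independent. The excess passed under 3 further normalizations of the deposited values (Fisher's exact test, largest p = 0.0232). These cannot undo the authors' own normalization, which stays open as a source. A base difference under a probe cannot be told apart, since probes reading higher were also in excess (Fisher's exact test, p = 0.00145) but the strain that would read lower is not given in the sources used here, and 0 of the genes within 10 Mb reading lower had several probes. Between 10 and 20 Mb, Pik3c2g read higher (0.521) in a single probe of its 2. A base difference under a probe would give such a split, but a single gene cannot decide. By the share in the window chance was not excluded, since 3 of 35 splits of the arrays gave as large a share, with 9.24% for the real split and 10.5% for the highest other, but that split had 10.3% elsewhere, and by the odds ratio against probes elsewhere, looked at after the share, the real split was the highest of the 35, at 2.07 against 1.93. Chance stays open, as the measures differ, and an effect of the receptor's loss on neighbouring genes was not tested.

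For the called gene lists, 13 of 35 splits of the arrays called as many lists, with 11 for the real split and 14 for the highest other, so chance was not excluded. A candidate explanation is that genes of a list vary together between mice, which the preset correlation understates, and 0 lists passed once the correlation was estimated. An effect of genotype on these lists stays open.

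With the values as deposited, 1 of 35 splits, the real one, called a probe (A2ml1), and the highest other split called 0. That is the smallest share that 35 splits can give, and it was counted after the call was seen. The other splits mix livers of low and high A2ml1, so they could hardly call this probe. The count therefore adds little to the adjusted p of the limma test and does not decide about chance. It was made with the values as deposited alone. The real split itself called 0 probes after quantile or scale normalization, in the ordinary test, with the replicate block and without any 1 knockout or wild-type liver 3. A2ml1 passed in 9 of 17 alternatives, and its difference lay between -0.848 and -0.701 in all of them.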
